A study of Mus musculus with 9 samples.

How the data were processed

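The data are 9 mouse arrays: 3 of normal GMP, 3 of L-GMP and 3 of L-GMP-derived cells. Groups were taken from sample titles and source labels. A GMP array without a number in its title was called replicate 1, and this number pairs it with nothing. The L-GMP-derived arrays have a code as title and L-GMP as source, and were assigned by elimination from the study's design text.

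The authors deposited a table of processed array intensities, one signal per probe set and array on a linear scale. Per the submitters' processing notes MAS5 (version 5) was used; background correction, summary method and scaling target are not given in the sources used here. The table holds 22690 probe sets, and 1917 of 204210 values (0.939%) are negative, down to -1890.55. MAS5's own signal algorithm gives no negative values, so the summary step behind these signals is unknown. The trimmed means of the arrays (2% at each end) lay within 4.02% of their mean, under the limit of 5% set beforehand, so the authors' scaling was kept. No detection calls were used here; signal relative to the floor was the only measure of whether a gene was above background.

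Signals below 62.4, the 25th percentile of all values, were set to that floor and log2 was taken. Probe sets above 111, the 40th percentile, on at least 3 of the 9 arrays were tested, after leaving out 64 control probe sets; 14578 remained. Because values near the floor are compressed, fold changes of dim genes are understated. Folds are taken between mean log2 signals and can differ from the ratio of the group means. Where 1 or more arrays of the lower group lay at the floor, this fold is a lower bound, given as "at least". It is not a bound on the ratio of group means, and ranks of such folds depend on the floor. Gene names come from the platform annotation of the probes: 20393 probe sets had 1 symbol, 691 had several and 1606 had none listed, and only those with 1 symbol were named. Entrez identifiers of 20364 of these matched RefSeq genes of the GRCm38.p6 assembly, and 0 symbols changed. Each gene stands for its probe set of highest mean log2 signal, which left 8965 tested genes. Probe sets whose names end in _x_at or _s_at can also bind related transcripts, and Ak4, Asns, Cad, H2-Aa, Hdc, Hpgd, Myb, Ndrg1, Ndufv1, Phgdh and Trib3 stand for such probe sets. Their signals, and those of the near-identical pair Hspa1a and Hspa1b and of the Ifitm and Slfn families, are uncertain for such reasons. Some genes of the lists have no named probe set and were not analysed here: 369 of 409 distinct list genes had one.

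Differences were tested with limma 3.58.1 (lmFit, contrasts.fit and eBayes with an intensity trend) in R 4.3.3, two-sided, on all 9 arrays with 1 shared estimate of the spread (6 residual degrees of freedom). P-values were adjusted by Benjamini and Hochberg over the tested probe sets of each comparison, with a threshold of 0.05. Gene lists, 23 in number, were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over all 69 tests of lists and comparisons. With an estimated correlation the adjusted p passed 0.05 in 4 of the 69 tests, against 34 with the preset one: the HoxA list in both comparisons with GMP, and the Myc and ribosome biogenesis list in both comparisons with L-GMP. This fall in calls is not due to correlation between genes alone, as given in the section on processing. A list with fewer than 5 tested members would have been given as values only.

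The genes named were fixed by rule: the 10 genes that rose most and the 10 that fell most among those past the threshold whose groups did not overlap, up to 4 members of each list past the threshold (or the 2 with the largest change where none passed), and 12 genes always. Fewer are given here, from the top of each ranking. Lists, rule, tests and alternatives were set before the data were examined, apart from those named in the closing section. Calls of several probe sets of a gene in opposite directions are counted for each comparison.

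Because both comparisons with GMP share their control arrays, unchanged groups were simulated 100 times against such controls, with the spread of each probe set from the fit. Control probe sets of Gapdh and beta-actin gave 3' to 5' and 3' to middle ratios, compared by exact permutation. Array scaling, floor, filter, the intensity trend, the arrays in the fit, weights per array, exclusion of probe sets with shared binding, a minimum fold, the mean over a gene's probe sets, a replicate block and omission of each array were tried as alternatives. The linear models were tested on simulated data with 200 changed probe sets among 14578. The noise was independent and normal, with the spread from the fit, and neither floor nor filter was applied. The rates that follow hold under these assumptions and do not cover losses at the floor. For L-GMP against GMP 89% of the 2-fold and 100% of the 4-fold changes were recovered, with 5.5% of calls false; for L-GMP-derived against GMP 90%, 100% and 4.52%; for L-GMP-derived against L-GMP 86%, 100% and 6.53%. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and drew figures. The number of arrays limits the precision of every value, and scan dates or batches were not used here.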

Results

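RNA levels were measured on 9 Affymetrix mouse arrays in 3 kinds of cell, with 3 arrays each. Granulocyte-macrophage progenitors (GMP) are bone marrow cells committed to making granulocytes and macrophages. L-GMP are cells with GMP features taken from the marrow of mice with leukemia driven by MLL-AF9, a fusion of the Kmt2a and Mllt3 genes. The remaining arrays, called L-GMP-derived here, carry a code as title and L-GMP as source. They were read as the cells that L-GMP gave rise to in culture, because the study's design text names such a kind and no other label fits it. This reading is a limit on every statement about them. Nothing in the labels says whether the 3 arrays of a group came from separate animals or cultures, so the p-values measure the spread between these arrays, which may be technical. Each array gave 22690 probe set signals, and 14578 probe sets passed the filter on dim signals. The number of arrays limits the precision of every value.

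The 3 kinds of cell separated along the first 2 principal components, which held 41.6% and 35.8% of the variance. Pairs of arrays from the same group correlated at 0.958 to 0.991 across probe sets, and pairs from different groups at 0.898 to 0.928. L-GMP-derived replicate 1 stood apart from its group: it correlated with replicates 2 and 3 at 0.958 and 0.964, against 0.989 between those. It differed by at least 2-fold from replicate 2 at 599 probe sets and from replicate 3 at 492, while replicates 2 and 3 differed so at 35. Controls added to every hybridization read, on average, 0.27 above the mean of the arrays (log2) on this array and 0.19 above it on GMP replicate 3, and between -0.16 and 0.01 on the others.

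**Figure D1:**
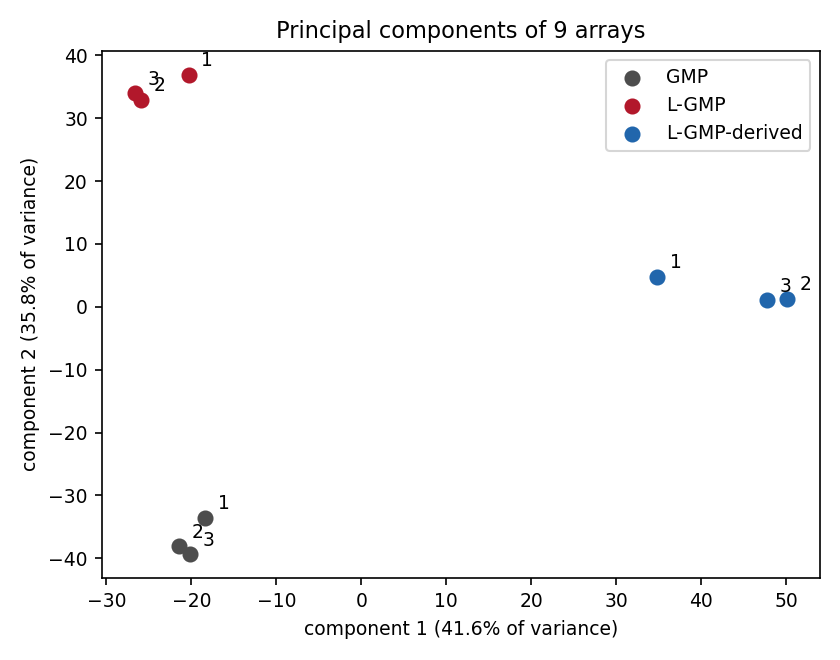
Principal components of the 14578 tested probe sets (log2 signal), with component 1 on the x axis (41.6% of the variance) and component 2 on the y axis (35.8%). Each point is an array, coloured by group and numbered by replicate; the groups do not mix, and L-GMP-derived replicate 1 lies apart from replicates 2 and 3.

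The comparison of L-GMP with GMP asks how leukemic cells with progenitor features differ from their normal counterparts. Hoxa9, which encodes a homeodomain transcription factor, had a signal of 5433 ± 162 (SD, n = 3) against 1599 ± 182 in GMP (3.41-fold, log2 fold change 1.77 ± 0.09 SE, adjusted p = 5.06e-07, limma). Meis1, which encodes a DNA-binding partner of Hox proteins, was 4.17-fold higher (2108 ± 176 against 505 ± 36.6). Nolc1, a gene of ribosome biogenesis, was 1.97-fold lower in L-GMP, and Myc 1.91-fold lower (605 ± 45.1 against 1155 ± 84.8). Of the 14578 probe sets, 3777 passed an adjusted p of 0.05, 1947 higher and 1830 lower in L-GMP, and 971 of them differed by at least 2-fold. The groups did not overlap at 46.2% of probe sets, where chance gives 10%.

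On the fitted scale, the largest rise was that of Hpgd, which encodes a prostaglandin-degrading dehydrogenase, at least 72.3-fold higher at 4517 ± 35.0 against 20.7 ± 4.80 (log2 fold change 6.18 ± 0.08 SE, adjusted p = 2.51e-11). Mycn, which encodes a transcription factor of the Myc family, was at least 61.0-fold higher, with a wide spread in L-GMP (4080.1 ± 1745). Dsp (desmoplakin) was 39.8-fold higher, Penk (proenkephalin) at least 34.7-fold and Mylk (myosin light chain kinase) 19.3-fold. The largest falls were those of Ppic, which encodes a peptidyl-prolyl isomerase, at least 25.6-fold lower, the inducible heat shock gene Hspa1a, 23.6-fold lower, the adenylate kinase gene Ak4, at least 22.3-fold, Tmem176b, 19.7-fold, and the cyclin gene Ccnd2, 16.9-fold. With single arrays left out the fold of Hspa1a ran from 17.0 (without L-GMP replicate 2) to 37.6 (without GMP replicate 1). A fold given as "at least" is set against a group with 1 or more arrays at the signal floor, which also shapes its rank.

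Of 9 tested genes on the HoxA list, 6 rose in L-GMP and 0 fell (the same counts adjusted over the list alone; camera adjusted p = 6.72e-06, adjusted p = 0.0412 with an estimated correlation). Pbx3 was at least 11.8-fold higher, Hoxa5 8.0-fold and Hoxa10 at least 3.75-fold. Hoxa7 was 1.44-fold higher (adjusted p = 0.0354), a call that ended when any of the 6 arrays was left out: its adjusted p was then 0.0616 (without GMP replicate 2) to 0.119 (without GMP replicate 1), and 0.0101 to 0.276 over all alternatives. On the list of MLL fusion targets, which shares Hox genes, Meis1 and Pbx3 with it, 12 of 18 rose and 1 fell (13 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.42e-07, adjusted p = 0.0857 with an estimated correlation). Both lists hold genes known from work on this leukemia, these samples possibly included, and are not independent evidence of direction. The Kmt2a probe set read 188 ± 10.9 in L-GMP and 178 ± 4.69 in GMP (adjusted p = 0.703). The Mllt3 probe set lay below the filter. Neither is a check of the fusion, since the part of the gene they read is not given in the sources used here.

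**Figure D2:**
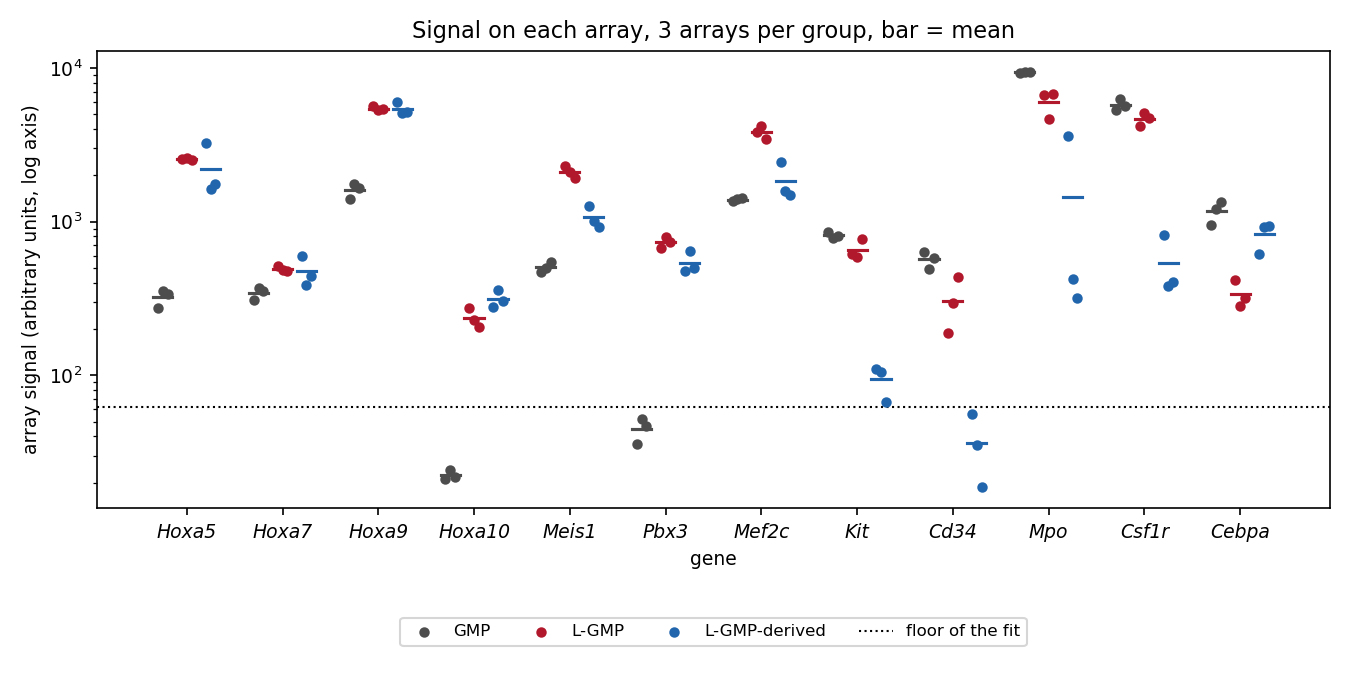
Signal on each array (y axis, arbitrary units, log scale) of 12 genes (x axis) in GMP, L-GMP and L-GMP-derived cells; points are arrays, bars are group means (n = 3) and the dotted line is the floor of the fit, 62.4. Hoxa9 averaged 1599 in GMP, 5433 in L-GMP and 5417 in L-GMP-derived cells, while Kit averaged 816, 657 and 93.9.

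Of 21 tested Myc and ribosome biogenesis genes, 0 rose and 15 fell (the same counts adjusted over the list alone; camera adjusted p = 9.21e-08, adjusted p = 0.0412 with an estimated correlation). Oxidative phosphorylation genes moved the same way, with 6 of 21 lower and none higher (the same counts adjusted over the list alone; camera adjusted p = 0.00661, adjusted p = 0.211 with an estimated correlation). Ndufv1, a subunit of complex I, was 1.76-fold lower and Cyc1 1.31-fold. Among p53 targets and Cdk inhibitors, 6 of 17 rose and none fell (the same counts adjusted over the list alone; camera adjusted p = 0.0177, adjusted p = 0.13 with an estimated correlation). That call ended without a filter on dim probe sets (adjusted p = 0.129; 0.003 to 0.13 over all alternatives). The Cdk inhibitor gene Cdkn1c was at least 6.47-fold higher, with a range with single arrays left out of at least 4.19 (without L-GMP replicate 1) to 9.39 (without L-GMP replicate 3), the p53 target Pmaip1 at least 5.76-fold and Cdkn2c 4.79-fold. Adhesion and homing genes also rose, 6 of 14 with none lower (9 rose and 0 fell adjusted over the list alone; camera adjusted p = 8.45e-04, adjusted p = 0.0857 with an estimated correlation). The integrin gene Itgb2 was 11.7-fold higher and the chemokine receptor gene Ccr1 at least 2.33-fold. Of 16 immediate early and heat shock genes 4 fell and none rose (the same counts adjusted over the list alone; camera adjusted p = 0.0278, adjusted p = 0.569 with an estimated correlation). Hspa1a read 195 ± 114 in L-GMP and 4852 ± 2804 in GMP, and Hspa1b, whose sequence is nearly identical, 494 ± 352 and 7329.6 ± 2666. The list's call ended without L-GMP replicate 2 (adjusted p = 0.0617), without GMP replicate 2 (0.182) and without GMP replicate 3 (0.0576; 1.02e-06 to 0.569 over all alternatives).

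Surface antigens of the GMP gate went both ways, with 3 higher and 1 lower of 8 (the same counts adjusted over the list alone, camera adjusted p = 0.202). Where cells were chosen by such antigens, that choice sets part of their levels, here and in the comparisons below. Cd34, a stem and progenitor antigen, was 1.95-fold lower (306 ± 124 against 568 ± 69.0, adjusted p = 0.0154), a call that ended without GMP replicate 1 (adjusted p = 0.0575), GMP replicate 3 (0.0571) or a filter on dim probe sets (0.0723; 0.00176 to 0.116 over all alternatives). The growth factor receptor gene Kit (657 ± 99.4 against 816 ± 41.7), the granule enzyme gene Mpo (6028 ± 1199 against 9366 ± 129) and Myb (7369 ± 295 against 7139.9 ± 204) did not pass the test (adjusted p = 0.247, 0.537 and 0.469). Mpo passed it, as lower, with only the 6 arrays in the fit (adjusted p = 0.00896, range 0.00896 to 0.774 over all alternatives). Its signals did not overlap (4647 to 6806 in L-GMP, 9224 to 9476 in GMP). The shared spread also took in the L-GMP-derived arrays, at 3581, 425 and 319, and no alternative left out single arrays of that group here. Stem cell markers numbered 2 higher and 4 lower of 14 (the same counts adjusted over the list alone; camera adjusted p = 0.821). Mycn was among the higher, and Hlf (at least 3.50-fold) and Tal1 (at least 2.61-fold) among the lower. Monocyte and macrophage genes went both ways, 3 higher and 4 lower of 15 (the same counts adjusted over the list alone; camera adjusted p = 0.972). Adgre1, which encodes the F4/80 antigen, was 8.17-fold higher and the transcription factor gene Klf4 7.10-fold lower. Of 15 myeloid transcription factors 3 rose and 2 fell (the same counts adjusted over the list alone; camera adjusted p = 0.859), Cebpa being 3.47-fold lower. Among granulocyte genes 1 rose and 2 fell of 15 (the same counts adjusted over the list alone, camera adjusted p = 0.416), and the plasma protein gene Hp was 3.17-fold higher.

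Of the other lists, STAT5 targets went both ways, 4 higher and 2 lower of 10 (4 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.626), with Ccnd2 16.9-fold and the kinase gene Pim1 4.09-fold lower and Id1 at least 3.76-fold higher. Amino acid response genes had 4 lower and none higher of 20 (the same counts adjusted over the list alone; camera adjusted p = 0.0556). Phgdh, which encodes the enzyme of the first step of serine synthesis, was 14.6-fold lower. Interferon response genes had 5 lower and none higher of 14 (the same counts adjusted over the list alone; camera adjusted p = 0.0556), led by Ifitm3 (15.6-fold) and the chemokine gene Cxcl10 (11.2-fold). With single arrays left out the fold of Cxcl10 ran from 7.54 (without GMP replicate 2) to 20.0 (without GMP replicate 1). The amino acid list passed the threshold without L-GMP replicate 1 (adjusted p = 0.0334) or GMP replicate 3 (0.0434; 0.0115 to 0.569 over all alternatives). The interferon list passed it without L-GMP replicate 3 (0.0365) or GMP replicate 1 (0.0172), with the floor at the 40th percentile (0.0113) and with the mean over each gene's probe sets (0.0140; 0.0074 to 0.294 over all alternatives). Among cell cycle genes 6 rose and 0 fell of 26 (5 rose and 0 fell adjusted over the list alone, camera adjusted p = 0.348). Among glycolysis and hypoxia genes 2 rose and 3 fell of 18 (the same counts adjusted over the list alone, camera adjusted p = 0.669). Among cholesterol synthesis genes 3 rose and 2 fell of 15 (the same counts adjusted over the list alone, camera adjusted p = 0.889). Among markers of erythroid cells and megakaryocytes 0 rose and 0 fell of 7 (the same counts adjusted over the list alone, camera adjusted p = 0.593). For B cell markers, 0 rose and 0 fell of 6 (the same counts adjusted over the list alone, camera adjusted p = 0.626). Of the T and NK cell markers, 0 rose and 1 fell of 8 (the same counts adjusted over the list alone, camera adjusted p = 0.794). Among markers of mast cells, eosinophils and basophils 1 rose and 1 fell of 6 (the same counts adjusted over the list alone, camera adjusted p = 0.887). Of MHC class II and dendritic cell genes, 1 rose and 2 fell of 5 (the same counts adjusted over the list alone, camera adjusted p = 0.593). The eosinophil granule gene Prg2 was 14.4-fold higher in L-GMP and H2-Aa 5.38-fold lower. Median, mean and test differed in sign for the stem cell, transcription factor, STAT5, cholesterol, T and NK cell, mast cell and MHC class II lists, none of which passed the threshold.

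The ratio of the 3' to the 5' control probe set of beta-actin, a measure of RNA quality, was 5.17 ± 0.355 in L-GMP and 7.37 ± 0.648 in GMP (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). The same ratio for Gapdh was 8.09 ± 3.05 and 7.86 ± 0.855 (exact p = 1). With the middle in place of the 5' probe set the ratios were 2.26 ± 0.291 and 4.23 ± 0.537 for beta-actin and 1.85 ± 0.0493 and 2.13 ± 0.101 for Gapdh (exact p = 0.1 each). Without GMP replicate 3, 2475 probe sets passed the threshold in place of 3777. Different probe sets of the same gene were called in opposite directions for 20 of the 498 genes with at least 2 called.

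The comparison of L-GMP-derived cells with GMP asks how cells grown from L-GMP differ from normal progenitors. Hoxa9 read 5417 ± 508 in L-GMP-derived cells (SD, n = 3), 3.39-fold above GMP (log2 fold change 1.76 ± 0.09 SE, adjusted p = 5.65e-07). Kit was 8.89-fold lower (93.9 ± 23.5 against 816 ± 41.7; log2 fold change -3.15 ± 0.19 SE, adjusted p = 1.59e-06), and Csf1r, which encodes the receptor for macrophage colony-stimulating factor, 11.5-fold lower (535 ± 247 against 5767 ± 507). Fdps, an enzyme gene of cholesterol synthesis, was 6.51-fold higher, and Asns (asparagine synthetase) 7.80-fold. In all, 3551 of the 14578 probe sets passed the threshold, 2036 higher and 1515 lower, with 954 at least 2-fold apart; groups did not overlap at 40.7% of probe sets, where chance gives 10%.

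On the fitted scale the largest rise was that of Hpgd (at least 102-fold), followed by Mylk (31.1-fold), Spats2 (at least 23.3-fold), Slfn4 (22.5-fold), a member of a family of similar genes, and F7, which encodes coagulation factor VII (at least 21.2-fold). The largest falls were those of Fos, an immediate early transcription factor gene (at least 57.3-fold; -1.80 ± 7.17 against 4383 ± 2674), Hspa1a (at least 54.9-fold), Hspa1b (49.1-fold), the potassium channel gene Kcnn4 (at least 35.0-fold) and Hdc, which encodes the enzyme that makes histamine (at least 31.6-fold). Leaving out single arrays moved the fold of Fos from at least 43.7 (without GMP replicate 2) to 94.7 (without GMP replicate 1) and that of Hspa1a from at least 43.4 (without GMP replicate 2) to 87.2 (without GMP replicate 1).

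On the HoxA list 7 of 9 genes rose and none fell (8 rose and 0 fell adjusted over the list alone; camera adjusted p = 2.93e-07, adjusted p = 0.0412 with an estimated correlation). Pbx3 was at least 8.54-fold higher, Hoxa11 at least 7.65-fold, Hoxa5 6.54-fold and Hoxa10 at least 4.98-fold, while Meis1 was 2.10-fold higher. Hoxa7 read 474 ± 108 against 343 ± 32.8 (adjusted p = 0.0662) and passed the threshold without L-GMP-derived replicate 2 (adjusted p = 0.0281; 0.0281 to 0.392 over all alternatives). MLL fusion targets counted 6 higher and 3 lower of 18 (8 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.0285, adjusted p = 0.282 with an estimated correlation), and the call ended without L-GMP-derived replicate 1 (adjusted p = 0.126) and without a filter on dim probe sets (0.286; 0.00845 to 0.286 over all alternatives). Here too the lists are not independent evidence of direction. Kmt2a read 159 ± 14.5 (adjusted p = 0.324).

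Of 15 cholesterol synthesis genes, 14 rose and none fell (the same counts adjusted over the list alone; camera adjusted p = 1.42e-12, adjusted p = 0.0963 with an estimated correlation). Msmo1 was at least 8.38-fold higher, Fdps 6.51-fold and Sqle, the squalene epoxidase gene, 5.99-fold. Of 20 amino acid response genes 16 rose and none fell (17 rose and 0 fell adjusted over the list alone; camera adjusted p = 6.21e-11, adjusted p = 0.112 with an estimated correlation). They included Trib3, a target of the stress factor ATF4 (at least 18.3-fold higher), Chac1 (at least 17.5-fold) and Asns. Glycolysis and hypoxia genes counted 11 higher and 1 lower of 18 (12 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.39e-05, adjusted p = 0.19 with an estimated correlation). Bnip3 was 4.02-fold higher and Ndrg1 3.16-fold lower. STAT5 targets counted 6 higher and 2 lower of 10 (the same counts adjusted over the list alone; camera adjusted p = 0.00794, adjusted p = 0.23 with an estimated correlation). Id1 was at least 11.4-fold higher and Cish, a feedback inhibitor gene, 9.29-fold. Myc and ribosome biogenesis genes counted 4 higher and none lower of 21 (the same counts adjusted over the list alone; camera adjusted p = 0.0372, adjusted p = 0.23 with an estimated correlation), Bop1 being 1.75-fold higher. That list lost its call without L-GMP-derived replicate 2 (adjusted p = 0.0967), GMP replicate 2 (0.0629) or GMP replicate 3 (0.0509) and after quantile normalization (0.0507; 0.00525 to 0.23 over all alternatives). Cell cycle genes counted 6 higher and none lower of 26 (7 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.0321, adjusted p = 0.414 with an estimated correlation), Aurka being 2.25-fold higher. The call ended without L-GMP-derived replicate 1 (adjusted p = 0.0511) or 3 (0.0564) and after quantile normalization (0.0727; 0.00773 to 0.414 over all alternatives). Among oxidative phosphorylation genes 7 rose and 2 fell of 21 (8 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.42).

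Of 15 monocyte and macrophage genes 8 fell and 4 rose (4 rose and 9 fell adjusted over the list alone; camera adjusted p = 0.00192, adjusted p = 0.139 with an estimated correlation). F13a1, a coagulation factor subunit gene of monocytes, was 24.6-fold lower, Klf4 at least 20.9-fold and Ms4a6c 12.5-fold. Myeloid transcription factors counted 7 lower and 3 higher of 15 (4 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.0257, adjusted p = 0.294 with an estimated correlation). Egr1, which is also on the immediate early and heat shock list, was at least 18.8-fold lower. That call ended without GMP replicate 3 (adjusted p = 0.0514) and without a filter (adjusted p = 0.0680, range 9.64e-06 to 0.068 over all alternatives). With single arrays left out the fold of Egr1 ran from at least 10.2 (without GMP replicate 2) to 53.4 (without GMP replicate 1). What is left open below on cell handling for the immediate early list holds for Egr1 too. Cebpa read 825 ± 183 against 1169 ± 199 (adjusted p = 0.101). Among granulocyte genes 1 rose and 3 fell of 15 (the same counts adjusted over the list alone, camera adjusted p = 0.173). Mpo was 11.9-fold lower (log2 fold change -3.57 ± 0.69 SE, adjusted p = 0.00407), but L-GMP-derived replicate 1 read 3581 where replicates 2 and 3 read 425 and 319. Without replicate 1 the fold was 25.4, and without replicate 3 it was 7.59. Camp, an antimicrobial peptide gene, was at least 10.8-fold lower, ranging from at least 7.14 (without GMP replicate 1) to 15.8 (without GMP replicate 2). Surface antigens of the GMP gate counted 2 lower, Kit and Cd34 (at least 9.05-fold), and none higher of 8 (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.138). Myb was 1.17-fold lower, a call that ended without an intensity trend in the fit (adjusted p = 0.0765; 8.90e-04 to 0.0765 over all alternatives).

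Immediate early and heat shock genes had 9 lower and none higher of 16 (0 rose and 10 fell adjusted over the list alone; camera adjusted p = 3.78e-05, adjusted p = 0.294 with an estimated correlation). The signals of these genes differed between GMP arrays: Hspa1a read 1615 on GMP replicate 1 and 6518 and 6423 on replicates 2 and 3. Interferon response genes had 6 lower and none higher of 14 (the same counts adjusted over the list alone; camera adjusted p = 0.00145, adjusted p = 0.13 with an estimated correlation). Cxcl10 was 11.1-fold lower, ranging from 7.47 (without GMP replicate 2) to 19.8 (without GMP replicate 1). Stem cell markers had 1 higher, Mycn (at least 17.1-fold, at least 10.8 without L-GMP-derived replicate 1), and 6 lower of 14 (the same counts adjusted over the list alone; camera adjusted p = 0.00661, adjusted p = 0.0963 with an estimated correlation). Gata2 was 5.63-fold lower. Among p53 targets and Cdk inhibitors 6 rose and 2 fell of 17 (the same counts adjusted over the list alone, camera adjusted p = 0.217), with Cdkn1a 7.37-fold higher. Among adhesion and homing genes 4 rose and 3 fell of 14 (the same counts adjusted over the list alone, camera adjusted p = 0.821). Among markers of erythroid cells and megakaryocytes 0 rose and 1 fell of 7 (the same counts adjusted over the list alone, camera adjusted p = 0.0691). For B cell markers, 0 rose and 1 fell of 6 (the same counts adjusted over the list alone, camera adjusted p = 0.626). Of the T and NK cell markers, 1 rose and 1 fell of 8 (the same counts adjusted over the list alone, camera adjusted p = 0.33). Among markers of mast cells, eosinophils and basophils 0 rose and 3 fell of 6 (the same counts adjusted over the list alone, camera adjusted p = 0.0897). Of MHC class II and dendritic cell genes, 1 rose and 1 fell of 5 (the same counts adjusted over the list alone, camera adjusted p = 0.267). The erythroid list passed the threshold without GMP replicate 3 (adjusted p = 0.0401; 0.0401 to 0.217 over all alternatives). The mast cell list passed it without L-GMP-derived replicate 1 (adjusted p = 0.0333) and without a filter (0.0259; 0.0148 to 0.271 over all alternatives). Median and mean differed in sign for the B cell list. Nkg7, a gene of cytotoxic cells, was 9.03-fold lower, and Thy1, a T cell and stem cell antigen gene, at least 4.83-fold higher, ranging from at least 3.64 (without L-GMP-derived replicate 3) to 7.61 (without L-GMP-derived replicate 1).

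The 3' to 5' ratio of beta-actin was 7.10 ± 0.140 in L-GMP-derived cells and 7.37 ± 0.648 in GMP (exact two-sided permutation p = 0.8), and that of Gapdh 7.21 ± 1.78 and 7.86 ± 0.855 (exact p = 0.5). With the middle in place of the 5' probe set these groups did not overlap: 3.01 ± 0.170 and 4.23 ± 0.537 for beta-actin, 1.86 ± 0.132 and 2.13 ± 0.101 for Gapdh (exact p = 0.1 each, the smallest possible). Without GMP replicate 3, 2306 probe sets passed the threshold, and with array weights 6912. Called probe sets of the same gene went in opposite directions for 25 of 415 genes.

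The comparison of L-GMP-derived cells with L-GMP shows what differed between the leukemic cells from marrow and those that grew in culture. Gnl3, a nucleolar protein gene, read 3204 ± 153 against 1713 ± 54.3 (SD, n = 3; 1.87-fold, log2 fold change 0.90 ± 0.07 SE, adjusted p = 1.20e-05), and Sqle, an enzyme gene of cholesterol synthesis, was 12.5-fold higher. Csf1r was 9.29-fold lower (log2 fold change -3.22 ± 0.24 SE, adjusted p = 8.30e-06). Hoxa9 read 5417 ± 508 against 5433 ± 162 (log2 fold change -0.01 ± 0.09 SE, adjusted p = 0.964), while Meis1 was 1.98-fold lower (log2 fold change -0.99 ± 0.13 SE, adjusted p = 3.79e-04). Of the 14578 probe sets 4354 passed the threshold, 2384 higher and 1970 lower, with 1115 at least 2-fold apart and 40.1% of all probe sets without overlap between groups (chance 10%).

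On the fitted scale the largest rise was that of Ifitm1, which encodes an interferon-induced membrane protein (at least 63.3-fold; 4735 ± 955 against 70.0 ± 28.6), followed by the actin regulator gene Enah (at least 31.1-fold), the fetal plasma protein gene Afp (at least 30.3-fold), F7 (at least 20.5-fold) and Ppic (at least 19.8-fold). The largest fall was that of Dsp (at least 56.1-fold), followed by Prg2 (at least 42.6-fold), Camp (at least 38.0-fold), Fos (at least 35.1-fold) and Penk (at least 34.0-fold). Leaving out single arrays moved the fold of Camp from 25.2 (without L-GMP-derived replicate 1) to at least 50.3 (without L-GMP-derived replicate 2). Replicate 1 was the only L-GMP-derived array at the floor for Camp, so 25.2 is not a lower bound. The fold of Fos moved from at least 26.0 (without L-GMP replicate 3) to at least 55.7 (without L-GMP replicate 2).

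**Figure D3:**
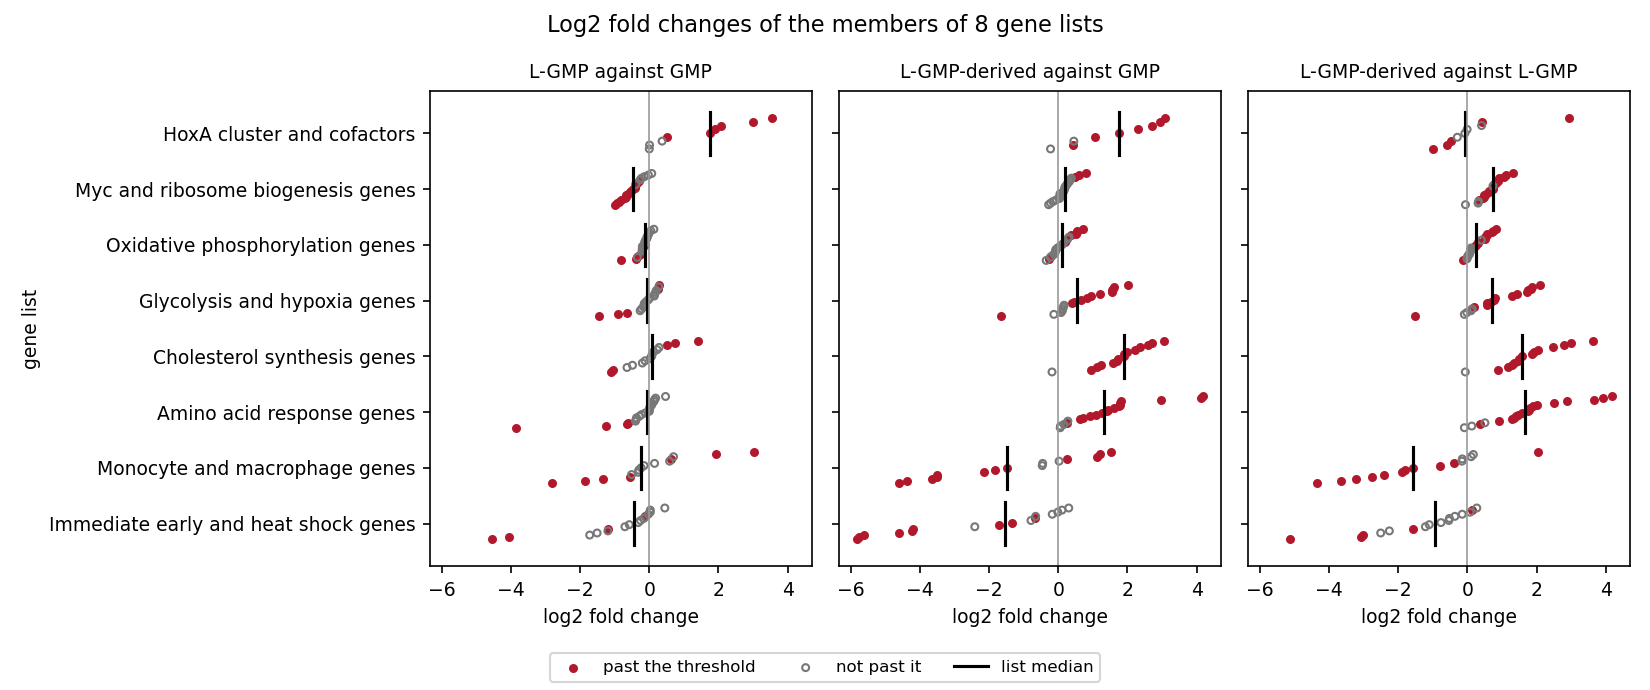
Log2 fold changes (x axis) of the tested members of 8 gene lists (y axis) in the 3 comparisons; each point is a gene, filled where its adjusted p was under 0.05, and the black line is the list median. Cholesterol synthesis genes had a median of 0.07 in L-GMP against GMP, 1.89 in L-GMP-derived against GMP and 1.58 in L-GMP-derived against L-GMP.

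Of 21 Myc and ribosome biogenesis genes 17 rose in L-GMP-derived cells and none fell (18 rose and 0 fell adjusted over the list alone; camera adjusted p = 2.83e-10, adjusted p = 0.0412 with an estimated correlation). Cad, an enzyme gene of pyrimidine synthesis, was 2.50-fold higher and Nolc1 2.17-fold. Cholesterol synthesis genes rose in 14 of 15 cases (the same counts adjusted over the list alone; camera adjusted p = 2.38e-11, adjusted p = 0.0963 with an estimated correlation), with Cyp51 8.01-fold higher. Amino acid response genes rose in 17 of 20 (18 rose and 0 fell adjusted over the list alone; camera adjusted p = 1.42e-12, adjusted p = 0.0963 with an estimated correlation), with Trib3 at least 18.3-fold and Phgdh 15.1-fold higher. Glycolysis and hypoxia genes counted 13 higher and 1 lower of 18 (14 rose and 1 fell adjusted over the list alone; camera adjusted p = 7.85e-06, adjusted p = 0.168 with an estimated correlation), led by Egln3 (4.33-fold). Oxidative phosphorylation genes counted 11 higher and 1 lower of 21 (13 rose and 1 fell adjusted over the list alone; camera adjusted p = 8.45e-04, adjusted p = 0.139 with an estimated correlation). Cyc1 was 1.67-fold higher. STAT5 targets counted 6 higher and 1 lower of 10 (the same counts adjusted over the list alone; camera adjusted p = 0.00945, adjusted p = 0.235 with an estimated correlation), with Pim1 9.90-fold and Cish 8.07-fold higher. That call ended with the floor at the 10th percentile (adjusted p = 0.0508; 0.00574 to 0.235 over all alternatives). Among cell cycle genes 5 rose and 1 fell of 26 (4 rose and 0 fell adjusted over the list alone, camera adjusted p = 0.292). Among p53 targets and Cdk inhibitors 5 rose and 7 fell of 17 (the same counts adjusted over the list alone, camera adjusted p = 0.626). Cdkn1c was at least 6.47-fold lower, ranging from at least 4.19 (without L-GMP replicate 1) to 9.39 (without L-GMP replicate 3), and Cdkn2c 6.07-fold lower.

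The HoxA list counted 2 higher and 3 lower of 9 (3 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.903). Hoxa11 was at least 7.65-fold higher. Hoxa5 read 2202 ± 899 against 2562 ± 49.3 (adjusted p = 0.371); without L-GMP-derived replicate 1, on which it read 3237, it passed the threshold with a log2 fold change of -0.61 (adjusted p = 0.00291; 0.00291 to 0.786 over all alternatives). Hoxa10 (adjusted p = 0.0565) passed it, as higher, without L-GMP replicate 1 (0.0288), without L-GMP-derived replicate 1 (0.0285), under quantile (0.0366) or median (0.0409) scaling, with the floor at the 40th percentile (0.0487) and without an intensity trend (0.0479; 0.0285 to 0.193 over all alternatives). Hoxa7 read 474 ± 108 against 491 ± 19.6 (adjusted p = 0.775). MLL fusion targets counted 1 higher and 10 lower of 18 (2 rose and 10 fell adjusted over the list alone; camera adjusted p = 0.00192, adjusted p = 0.157 with an estimated correlation), with the RNA-binding protein gene Cpeb2 4.70-fold and Id2 at least 4.48-fold lower. Neither list is independent evidence of direction. Kmt2a read 159 ± 14.5 against 188 ± 10.9 (adjusted p = 0.149).

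Monocyte and macrophage genes counted 10 lower and 1 higher of 15 (the same counts adjusted over the list alone; camera adjusted p = 8.14e-05, adjusted p = 0.0963 with an estimated correlation). Ms4a6c was 20.3-fold lower and Mpeg1, a pore-forming protein gene of macrophages, at least 12.7-fold. Granulocyte genes counted 6 lower and 2 higher of 15 (2 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.0257, adjusted p = 0.42 with an estimated correlation), a call that ended without L-GMP replicate 1 (adjusted p = 0.116; 0.01 to 0.42 over all alternatives). Mpo was 7.55-fold lower, 16.1-fold without L-GMP-derived replicate 1 and 4.81-fold without replicate 3. That call ended without a filter (adjusted p = 0.0653; 9.70e-08 to 0.0653 over all alternatives). Myeloid transcription factors counted 8 lower and 1 higher, Cebpa (2.43-fold), of 15 (2 rose and 9 fell adjusted over the list alone; camera adjusted p = 0.0135, adjusted p = 0.255 with an estimated correlation). Adhesion and homing genes counted 7 lower and 1 higher of 14 (the same counts adjusted over the list alone; camera adjusted p = 0.0136, adjusted p = 0.114 with an estimated correlation), Cd24a being 2.67-fold lower and the chemokine receptor gene Cxcr4 2.42-fold. Surface antigens of the GMP gate had 5 lower and none higher of 8 (0 rose and 7 fell adjusted over the list alone; camera adjusted p = 8.45e-04, adjusted p = 0.0963 with an estimated correlation). Kit was 7.11-fold lower and Cd34 at least 4.63-fold. Stem cell markers had 4 lower and none higher of 14 (the same counts adjusted over the list alone; camera adjusted p = 0.00794, adjusted p = 0.0991 with an estimated correlation), Gata2 being 7.17-fold lower. Immediate early and heat shock genes had 4 lower and 1 higher of 16 (1 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.0246, adjusted p = 0.569 with an estimated correlation), a call that ended without L-GMP-derived replicate 2 (adjusted p = 0.0611), with the floor at the 40th percentile (0.0575) and without a filter (0.0588; 2.69e-04 to 0.569 over all alternatives). Myb was 1.21-fold lower.

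Among interferon response genes 1 rose and 3 fell of 14 (the same counts adjusted over the list alone, camera adjusted p = 0.42). Among markers of erythroid cells and megakaryocytes 0 rose and 2 fell of 7 (the same counts adjusted over the list alone, camera adjusted p = 0.314). For B cell markers, 0 rose and 1 fell of 6 (0 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.425). Of the T and NK cell markers, 1 rose and 2 fell of 8 (1 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.388). Among markers of mast cells, eosinophils and basophils 0 rose and 2 fell of 6 (the same counts adjusted over the list alone, camera adjusted p = 0.249). Of MHC class II and dendritic cell genes, 1 rose and 1 fell of 5 (1 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.626). Median, mean and test differed in sign for the HoxA and interferon lists, neither past the threshold. Cpa3, a mast cell protease gene, was at least 12.4-fold lower, ranging from at least 7.32 (without L-GMP replicate 3) to 22.0 (without L-GMP replicate 1). The 3' to 5' ratio of beta-actin was 7.10 ± 0.140 in L-GMP-derived cells and 5.17 ± 0.355 in L-GMP (exact two-sided permutation p = 0.1, the smallest possible). That of Gapdh was 7.21 ± 1.78 and 8.09 ± 3.05 (exact p = 0.7). The ratio of the 3' to the middle probe set was 3.01 ± 0.170 and 2.26 ± 0.291 for beta-actin (exact p = 0.1) and 1.86 ± 0.132 and 1.85 ± 0.0493 for Gapdh (exact p = 1). Called probe sets of the same gene went in opposite directions for 17 of 638 genes.

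Calls against GMP were set side by side to see what L-GMP and L-GMP-derived cells have in common. Among 1947 probe sets higher in L-GMP and 2036 higher in L-GMP-derived cells, 810 were higher in both, where independent lists would share 272; 572 were lower in both, where 190 would be. Opposite calls numbered 105 (202 if independent) and 126 (256 if independent). The covariance of the fold changes across probe sets was 0.174, against 0.0156 ± 0.000444 (SD of 100 simulations) for unchanged groups sharing the same GMP arrays. The correlation, 0.469, was not above the 0.50 ± 0.0106 (SD) that shared controls alone gave. That simulated value arises whatever the size of the noise, so it does not show that shared controls account for the relation. The 3 GMP arrays cannot be split into sets of at least 2, so part of the excess overlap may come from the shared controls. Probe sets are not independent replicates.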

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

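Counts of probe sets past the threshold (3777, 3551 and 4354 in the order L-GMP against GMP, L-GMP-derived against GMP, L-GMP-derived against L-GMP) stayed within 1.5 times under both other scalings, other floors, other filters, no trend, fits on 6 arrays and exclusion of probe sets with shared binding. Asking for at least 2-fold left 971, 954 and 1115, by construction. Weights per array gave 6912 for L-GMP-derived against GMP; the cause was not tested. With single arrays left out the counts ran from 2475 to 3100, from 2306 to 4456 and from 3341 to 5478; the 4456 and 5478 came without L-GMP-derived replicate 1. With the replicate number as a block the counts were 1916, 1750 and 3272. In that block the GMP array without a number had a level of its own, which in effect took it out of both comparisons with GMP. The block levels also used up residual degrees of freedom. How much each of these adds was not tested. The labels tie the numbers to no shared animal or day. L-GMP and L-GMP-derived arrays of the same number correlated at -0.309, -0.133 and -0.270 in their deviations from group means. With GMP replicates 2 and 3, L-GMP arrays of the same number gave 0.170 and -0.129, and L-GMP-derived arrays -0.276 and -0.019. The numbers were therefore not taken to pair the arrays.

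The list tests past the threshold fell from 34 to 4 with an estimated correlation. The correlation of a list's own genes does not account for every loss, since some lists estimated below the preset 0.01 lost calls too. These included p53 targets (estimate 0.00387) and adhesion genes (-0.0305) in L-GMP against GMP, and stem cell markers (-0.0222) in L-GMP-derived against GMP. The HoxA list in L-GMP against GMP, estimated at -0.00456, kept its call, yet its camera adjusted p rose from 6.72e-06 to 0.0412. The fall from 34 to 4 is therefore not a measure of correlation between genes alone. What else the estimated setting changes was not tested. The covariance of the fold changes against GMP, less that expected from shared controls, was 0.159; it was 0.197 and 0.119 with the floor at the 10th and 40th percentile, 0.105 without a filter, 0.193 with a stricter filter and 0.145 to 0.174 with single arrays left out, whose SD served as its spread. The cause was not tested. The log2 difference in the 3' to 5' ratio of beta-actin, -0.51 for L-GMP against GMP and -0.05 for L-GMP-derived against GMP, became -0.90 and -0.48 with the middle probe set in place of the 5'; the cause was not tested. The other ratio differences moved by less than the spread between replicates.

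No named gene changed direction while past the threshold, under the other scalings and floors, without a filter or trend, with 6 arrays in the fit, a block or an omitted array. Of the comparisons of a named gene with an alternative that omitted no single array, 104 lost a call, 8 gained a call and 2152 did neither. These include the fits on only the 6 arrays compared. With a single array left out, 139 lost a call, 4 gained a call and 1555 did neither. For list tests the numbers were 37, 6 and 509, and with a single array left out 11, 6 and 397. Dim signals limit what the arrays show: in the fits, values below the floor have no order.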

Other observations

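The tests of cell handling and of array scaling for immediate early genes, of Mycn, and of L-GMP transcripts at the share that the shift of replicate 1 needs were chosen only after the results were seen, as were the interval of the excess of L-GMP transcripts, its value per gene and the genes named next.

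Many probe sets set L-GMP apart from both other groups, and many did so for each of the others. L-GMP-derived cells were higher than both other groups at 962 probe sets and lower at 753. GMP was higher than both at 572 and lower at 810. In 1011 the signal was lower in L-GMP than in GMP and in L-GMP-derived cells, and in 816 of these the last were not called apart from GMP. Ppic read 6.05 ± 11.8 in L-GMP against 1602 ± 62.4 in GMP and 1367 ± 637 in L-GMP-derived cells (SD, n = 3), and Phgdh 299.7 ± 97.1 against 4214 ± 79.7 and 4386 ± 387. Ifitm1 read 70.0 ± 28.6, 1059.7 ± 37.0 and 4735 ± 955 in the same order. In 914 the signal was higher in L-GMP than in both, and in 656 of these the others were not called apart. Dsp read 3519 ± 399.9 in L-GMP, 88.5 ± 11.3 in GMP and 32.2 ± 17.2 in L-GMP-derived cells, and the eosinophil granule genes Prg2 2669 ± 286, 221 ± 166 and 22.0 ± 7.41 and Prg3 994 ± 166, -14.7 ± 7.19 and -39.3 ± 7.91. Independent lists would share 299 and 263 probe sets. The L-GMP arrays enter both comparisons, which alone gives a covariance of the fold changes of -0.0157, where -0.179 was observed. The correlation, -0.479, was no stronger than the -0.501 ± 0.0110 (SD of 100 simulations) that shared arrays alone gave. Such a simulated correlation arises whatever the size of the noise, so it does not show that shared arrays account for the relation. The 3' to 5' ratio of beta-actin also set L-GMP apart, with 5.17 against 7.37 in GMP and 7.10 in L-GMP-derived cells (exact p = 0.1 each, and 0.8 between GMP and L-GMP-derived cells). That of Gapdh did not (8.09, 7.86 and 7.21; exact p = 1 and 0.7). With the middle probe set in place of the 5', L-GMP was not the only group apart: beta-actin gave 2.26, 4.23 in GMP and 3.01 in L-GMP-derived cells (exact p = 0.1 for each pair), and Gapdh 1.85, 2.13 and 1.86, with GMP apart from both (exact p = 0.1 each). What RNA quality adds to this pattern was not tested and stays open.

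With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many calls. The real splits called 3777, 3551 and 4354 probe sets, and the highest of the others 0, 0 and 1. Every other split mixes both kinds of cell within each group, so their difference enters the spread and few calls were assured. The low counts therefore decide nothing.

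L-GMP-derived replicate 1 stood apart from replicates 2 and 3. The tables argue against noise of dim probe sets, since in the third of probe sets with the highest signal its median difference from the others was 2.29 times that between them. After quantile normalization its mean correlation with them was still lower by 0.0283. A correlation hardly responds to the scale of an array, so this value decides nothing about array scaling. RNA of L-GMP cells as the whole of its shift is also argued against: that would need a share of 27.3% (log2 slope; 23.8% on linear signals, while toward GMP the slopes were 24.1% and 25.3%), and the upper bound below is 6.84. The 21 probe sets bright in L-GMP (a limit not planned) and at least 16-fold lower in replicates 2 and 3 exceeded those by a median of 3.03 points of the L-GMP level (97.3% interval 0.480 to 6.84, from order statistics), and the 17 named genes among them by 3.82 points (95.1% interval 0.801 to 6.84). A small share stays open: the planned reading, a median under 5 points, argued against it, but the interval reaches 5 points, the choice of probe sets low in replicates 2 and 3 itself favours an excess, and single genes went far apart (Mpo at 59.4% of the L-GMP level, Camp at -0.0570%). Both intervals of the excess treat the chosen probe sets or genes of 1 array as independent draws. They measure the spread between those transcripts, not that between arrays. The argument against L-GMP RNA as the whole of the shift rests on them. No biological explanation was tested.

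Of 16 immediate early and heat shock genes 9 were lower in L-GMP-derived cells than in GMP and 7 were not called (adjusted p = 0.294 with an estimated correlation). The list's median log2 fold change was still -1.53 under the scaling that brought it nearest to 0. The trimmed means of the arrays already lay within 4.02% of their mean, so rescaling could hardly move this median and decides nothing. Handling of cells that differed between preparations stays open: the 9 had a median SD of 1.16 between GMP arrays (log2), 0.91 between L-GMP arrays and 0.13 between L-GMP-derived arrays. That the first lay above 100% of 10000 random lists matched on mean signal decides nothing, since the spread had been seen before and the random lists were not matched for genes regulated together. Growth in culture, which the design names for the last group, stays open and was not tested.

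Of 20 amino acid response and 15 cholesterol synthesis genes 16 and 14 were higher in L-GMP-derived cells than in GMP, and 17 and 14 than in L-GMP, though with an estimated correlation neither list passed the threshold (adjusted p = 0.112 and 0.0963, and 0.0963 for both). The array of replicate 1 alone is argued against, since without it the lowest of the 4 list medians was 1.14 (log2). Under the other scalings the lowest was 1.30. With arrays already scaled so nearly alike, rescaling could hardly change it, so this decides nothing about array scaling. Growth in culture stays open as an untested hypothesis, since every L-GMP-derived array shares it.

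A hypothesis that more Mycn raises Myc and ribosome biogenesis genes found no match in L-GMP. Mycn read 4080.1 ± 1745 there against 13.2 ± 14.8 in GMP, but the list's median log2 fold change was -0.47, and Myc itself was lower. In L-GMP-derived cells, where Mycn was at least 17.1-fold higher than in GMP, 4 of the 21 list genes were higher and 0 lower (median 0.18, camera adjusted p = 0.0372, 0.230 with an estimated correlation), so the hypothesis stays open there. Against L-GMP these cells had Mycn lower by 3.56-fold, a call that ended under 6 alternatives (highest adjusted p = 0.0888, without a filter), and the list higher (17 of 21). Mycn on single L-GMP arrays read 5772, 4182 and 2286.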
